A study of Mus musculus with 11 samples.

How the data were processed

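Total RNA was measured by sequencing in primary lung fibroblasts, connective tissue cells grown out from the lungs of single mice. The 11 samples came from 6 mice lacking cGAS (KO: 3 females and 3 males) and 5 wild-type mice (WT: 2 females and 3 males), so that each sample is a separate animal. The cells were kept at 37 °C in 5% CO2 and 5% O2 in DMEM/F12 medium with 15% serum, and ribosomal RNA was depleted before library construction, per the labels' protocols. The labels' extraction text speaks of tissue rather than cultured cells, which could not be settled from the sources used here.

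The authors deposited 1 table of raw whole-number counts per sample, with no normalization. Reads were trimmed with Trim Galore and aligned with STAR to GRCm39, per the submitters' processing notes, which give no versions. The counting program, its strand setting, its treatment of reads with several genomic matches and the gene annotation were not given in the sources used here. The deposited counts of all samples came from coordinate-sorted alignments of 1 pipeline run, per the file headers. Each table held 58223 entries, of which 56980 were Ensembl genes and 1243 were repeat subfamilies. Because the sharing of reads among repeat copies is unknown, and because overlapping and antisense genes cannot be separated without strand, values of repeats, overlapping genes and close paralogs such as the replication histones are uncertain. Female and male libraries carried differently styled names, so a sex difference may coincide with a preparation difference, and these cannot be told apart.

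Gene symbols came from the GENCODE vM21 annotation of the older GRCm38 build, which was used only for names and for which genes lie near each other. It matched 52073 of the 56980 gene IDs and left 4907 without a symbol. A further 58 list genes were matched through older symbols. No coordinates are given, because the builds differ.

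Total counts per sample ran from 27261958 to 48039328. A count of 0 in a library allows a level of up to 3 counts, or 0.0624 to 0.110 CPM (counts scaled by library size) across the libraries. This floor covers counting error only, since reads without molecular identifiers are not independent molecules. CPM values were computed here from the deposited counts with TMM-scaled library sizes (scaling factors 0.951 to 1.04). Replicates were compared before averaging: the chi-square per degree of freedom between libraries of 1 group ran from 12.1 to 145, over entries with at least 20 counts in the pair, and no libraries were identical.

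Differences were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM scaling over all entries, filterByExpr with a minimum count of 10) in R 4.3.3. Genes and repeats were fitted together. The contrast of KO and WT over both sexes, the contrast of males and females, and the repeat results used a model with sex and genotype (8 residual degrees of freedom). The male, female and genotype-by-sex contrasts used a model with a mean per genotype and sex (7 residual degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method over all entries tested, with a threshold of 0.05. SD is given for CPM and SE for fitted log2 fold changes, which are KO minus WT unless stated.

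Before the data were examined, 25 gene lists were fixed: nucleic acid sensing by the cGAS-STING pathway, interferon-stimulated genes, inflammation and secreted senescence factors, NF-κB targets, p53 targets and senescence, proliferation, replication histones, heterochromatin and lamina, DNA repair, collagen and matrix, contractile genes, lung fibroblast identity, markers of epithelial cells, endothelial cells, leukocytes and macrophages, mesothelial cells, pericytes, skeletal muscle, cartilage and adipocytes, NRF2 targets, the integrated stress and unfolded protein responses, immediate early genes, cholesterol synthesis and uptake, and mitochondrially encoded genes. Each was tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists, and again with a correlation estimated for each list. Member counts are given over all genes tested and adjusted over the list alone. The mean log2 CPM of a list was its score. Scores, the share of counts on LINE-1 and on other repeat families were tested with a two-sided exact permutation of genotype within sex (200 arrangements, smallest p 0.005; with males alone 20 arrangements, smallest p 0.1). The share of called genes within 10 Mb of Cgas was tested with a two-sided Fisher exact test.

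The rule for named genes was also fixed in advance. It took Cgas; the 10 highest and 10 lowest genes over both sexes past the threshold with an average log2 CPM of at least 1 and the same sign in each sex, leaving out gene models without a name of their own; the 3 members of each list with the smallest p; 5 and 5 genes in every other contrast; 5 and 5 repeat subfamilies; and sex-linked genes and Nnt as checks. Where too few passed, the genes with the smallest p were taken and are given as not past the threshold. Some genes that the rule takes are left out of the text. Insig1, Hmgcs1, Adgre1, Cd68, Lyz2, Cnn1, Acta2 and RLTR4_Mm, and the repeat subfamilies called in males, were chosen after their values were seen, as were genes that make up small counts under other settings.

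On simulated counts, the fit over both sexes found 62% of 100 genes changed by 1 on the log2 scale and 88% of 100 changed by 2, and 2.60% of its calls were false. In males these values were 42%, 85% and 10.6%, in females 44%, 76% and 4.76%, for the genotype-by-sex contrast 6%, 64% and 7.89%, and for sex 69%, 83% and 5.59%. All libraries were simulated with the same spread for a gene, so none diverged as WT female 2 does in the real data. The power for the real libraries is thus not shown. A list of 20 genes moved by 0.5 was found by camera with the preset and with the estimated correlation, and 0 of 20 other lists was called. Genes were simulated independently of each other, so this does not test lists whose members move together. In the real data the estimated correlation was 0.648 for the cholesterol genes and 0.899 for proliferation. The permutation test of the LINE-1 share found 97% of simulated shifts of 0.4 (log2) and called 6.5% of sets with no shift. These simulations used an SD of 0.15 (log2) in every group and a shift larger than the observed −0.20. The real WT females spread more widely, at LINE-1 shares of 0.624% and 0.939%, so the power for the real shares is not shown.

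Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a filter of 1 CPM in 5 libraries, limma-voom with sample quality weights, scaling from gene counts alone, no sex term, the equal-weight mean of both sexes, each sex fitted alone, the replicate number as a block, fry and estimated correlations for the lists, other denominators and windows, and leaving out each library in turn. A leukocyte or proliferation score as a covariate, and leaving out WT female 2 together with KO male 1, were added after seeing the data. No sample was left out of the reported values.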

Results

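The series asks which transcripts change in primary lung fibroblasts of mice that lack cGAS, the cytosolic DNA sensor, and its title names premature aging, LINE-1 derepression and inflammation. RNA sequencing counts of genes and repeats were analysed from 6 KO animals (3 females, 3 males) and 5 WT animals (2 females, 3 males). Total counts were 45278144, 47194962 and 27261958 in the KO females and 46474688, 45832950 and 48039328 in the KO males. They were 31621959 and 41434450 in the WT females and 40182892, 45137219 and 37740674 in the WT males. Repeats took 5.31% to 10.2% of the counts, with the highest share in WT female 2, which also had the lowest median correlation with the other libraries (0.960).

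Cgas (ENSMUSG00000032344), the targeted gene, was read in every library first. It had 52 to 111 counts in the KO libraries and 222 to 403 counts in the WT libraries. This corresponds to 2.07 ± 0.25 CPM (SD, n = 6) against 8.26 ± 1.76 CPM (SD, n = 5). Every KO library was below every WT library. Cgas fell by 1.99 on the log2 scale (SE 0.16, edgeR adjusted p = 0.00102), by 1.85 in males (SE 0.21, edgeR adjusted p = 0.0349) and by 2.17 in females (SE 0.23, edgeR adjusted p = 0.0407). Counts per gene do not show which exons the remaining reads cover. The call over both sexes held without each library in turn. It was lost with the replicate number as a block (log2 −1.96, edgeR adjusted p = 0.0739) and with a leukocyte score as a covariate (log2 −2.07, edgeR adjusted p = 0.114). Replicate numbers showed no pairing of KO and WT libraries within sex. Deviations from group means correlated at −0.145 to 0.0731 for the same number and −0.238 to 0.192 for other pairs. The block also leaves fewer residual degrees of freedom, so a call lost with it does not show a block effect. The male call was lost without KO female 2, KO female 3, KO male 1, KO male 2 or WT male 1 (edgeR adjusted p = 0.0745, 0.0518, 0.212, 0.159 and 0.134 for Cgas). The female call was lost without KO female 1, KO female 2 or KO female 3 (0.403, 0.240 and 0.409), without KO male 1, KO male 2 or KO male 3 (0.132, 0.146 and 0.140) and without WT female 2 or WT male 2 (0.169 and 0.134).

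Genes of cholesterol synthesis and uptake were higher as a group in KO fibroblasts. Of 20 measured members 19 had a positive fold change, and the mean was 0.65 (log2). Nsdhl, a sterol dehydrogenase, was at 24.9 ± 2.10 CPM in KO (SD, n = 6) and 14.8 ± 3.09 CPM in WT (SD, n = 5). Its log2 difference was 0.75 (SE 0.13). Idi1, the isopentenyl diphosphate isomerase, was at 41.2 ± 5.65 against 22.6 ± 5.31 CPM. Fdps, which makes farnesyl diphosphate, was at 44.1 ± 6.86 against 24.6 ± 5.66 CPM.

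No member of this list passed over all genes tested (edgeR adjusted p = 0.179 for those named), and 19 of 20 were higher when adjusted over the list alone. The camera test gave an adjusted p of 8.98e-31, and adjusted p = 0.191 with an estimated correlation. The list score was 5.90 to 6.26 in the 6 KO libraries and 5.06 to 5.83 in the 5 WT libraries, without overlap (exact permutation p = 0.01, adjusted p = 0.0938 over the 25 lists). DESeq2 called 18 members higher over all genes, and limma-voom with sample quality weights called 19. The voom weight was 5.52 for WT male 2 and 0.141 to 0.552 for the other WT libraries. The WT side of the limma-voom result therefore rests largely on WT male 2. Leukocyte and macrophage markers were higher in KO as well (camera adjusted p = 8.3e-08; adjusted p = 0.484 with an estimated correlation). With their score as a covariate, chosen after seeing the data, the KO coefficient of the cholesterol score went from 0.676 (SE 0.133) to 0.405 (SE 0.156).

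**Figure D1:**
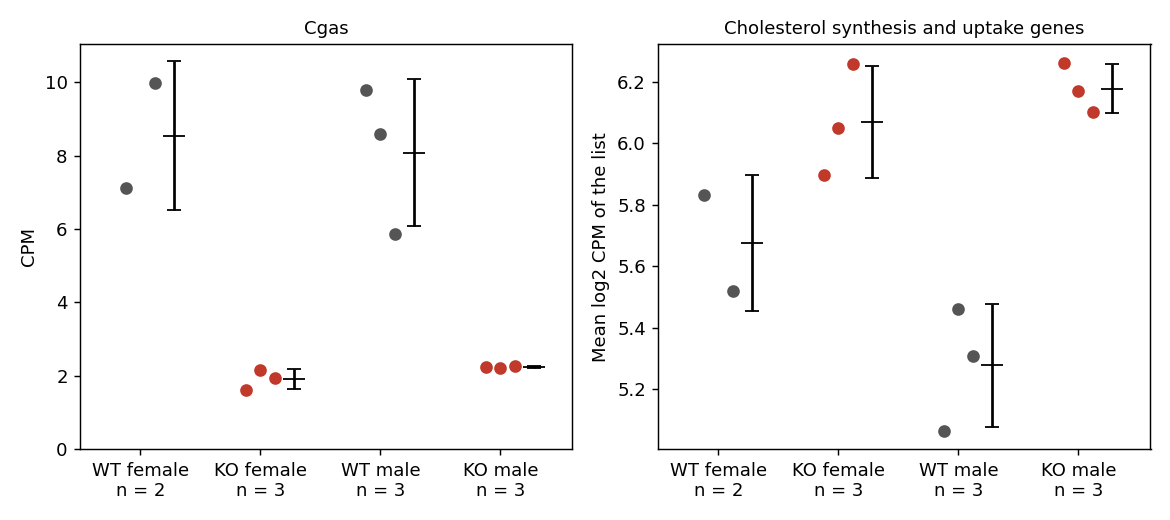
Cgas in CPM (left) and the mean log2 CPM of the cholesterol synthesis and uptake genes (right) by group, with 1 point per library and the mean ± SD in black beside the points. Cgas lies between 1.61 and 2.26 CPM in KO libraries and between 5.87 and 9.98 CPM in WT libraries, and the cholesterol score of every KO library (5.90 to 6.26) is above that of every WT library (5.06 to 5.83).

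Among single genes over both sexes, the higher side of those named was mostly sterol genes, none past the threshold (edgeR adjusted p = 0.179). Besides the genes above these were Sqle at a log2 difference of 0.75 (SE 0.14) and Lss at 0.89 (SE 0.18), which belong to the list, and Acat2 at 0.80 (SE 0.15) and Tm7sf2 at 0.69 (SE 0.14), which act in the same pathway. Pcdhb22, a protocadherin, was at 0.56 (SE 0.10). On the lower side, also not past the threshold, were Cyp26b1, a retinoic acid hydroxylase, at −1.72 (SE 0.38), the receptor phosphatase Ptpru at −0.89 (SE 0.15) and the guidance factor Ntn1 at −0.69 (SE 0.13). Zfp469 (−0.60), Tchp (−0.60), Nptxr (−0.53), the lung mesenchyme factor Foxf1 (−0.50) and Wdfy1 (−0.40) followed.

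Of 22298 entries tested with edgeR, 1 passed (Cgas), and 3827 (17.2%) had an unadjusted p under 0.05. DESeq2 called 521 (382 higher, 139 lower), limma-voom with sample quality weights called 3259, and without WT female 1 the count was 1678.

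The sensing and inflammatory lists, which the series title bears on, moved by small amounts. Nucleic acid sensing genes were higher as a group, 16 of 21 being positive, with Aim2 at 0.43 (SE 0.13), Enpp1, which degrades cGAMP, at 0.47 (SE 0.15) and Ikbke at 0.40 (SE 0.15). The camera test gave an adjusted p of 0.00538 there, and adjusted p = 0.484 with an estimated correlation. Interferon-stimulated genes were positive in 29 of 39 cases (camera adjusted p = 0.00135; adjusted p = 0.617 with an estimated correlation), with Trim30a at 0.56 (SE 0.16), Dhx58 at 0.41 (SE 0.13) and Irf9 at 0.31 (SE 0.10). NF-κB targets were positive in 16 of 20 cases (camera adjusted p = 0.00104; adjusted p = 0.484 with an estimated correlation), with Nfkbie at 0.53 (SE 0.16), Nfkb1 at 0.22 (SE 0.07) and Tnfaip2 at 0.29 (SE 0.10). The list of inflammation and secreted senescence factors was not called (20 of 44 positive, camera adjusted p = 0.355), and 3 members were lower when adjusted over the list alone, among them the growth factor Ereg at −0.62 (SE 0.14) and the prostaglandin synthase Ptgs2 at −1.14 (SE 0.30). In these 4 lists edgeR passed 0 members over all genes, and 0 of the sensing, interferon and NF-κB genes when adjusted over the list alone. DESeq2 called 1 interferon-stimulated gene higher and 3 inflammation genes lower, and limma-voom with sample quality weights called 5 sensing, 4 interferon and 7 NF-κB genes higher and 1 interferon, 1 NF-κB and 2 inflammation genes lower. The interferon call was lost without WT male 1 (camera adjusted p = 0.0983), and the sensing call without WT female 2 (camera adjusted p = 0.0501). With the leukocyte score as a covariate the sensing and NF-κB calls were lost (camera adjusted p = 0.778 and 0.334), and the interferon list was called lower (camera adjusted p = 0.0485). Without WT female 2 and KO male 1 together, also chosen after seeing the data, the sensing call was lost (camera adjusted p = 0.115).

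By sex, none of the sensing, interferon and NF-κB lists was called in females (camera adjusted p = 0.101, 0.607 and 0.331), where 17 of 21, 23 of 39 and 14 of 20 members were positive. In males each was called (camera adjusted p = 0.0248, 0.000231 and 0.000231; adjusted p = 0.553, 0.578 and 0.436 with an estimated correlation). There 1 sensing, 8 interferon and 7 NF-κB genes were higher, and 1 interferon gene lower, when adjusted over the list alone. The difference between the sexes gave camera adjusted p = 0.516, 0.00735 and 0.0155, and adjusted p = 0.754, 0.614 and 0.568 with an estimated correlation.

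Lists bearing on senescence, chromatin and genome maintenance showed the following. The list of p53 targets and senescence genes was lower as a group (5 of 24 positive, camera adjusted p = 0.00189; adjusted p = 0.484 with an estimated correlation). Adjusted over the list alone, Sesn1, a stress-induced sestrin, was higher at 0.67 (SE 0.15) and the exonuclease Aen lower at −0.48 (SE 0.12), whereas Mdm2, which degrades p53, was at −0.22 (SE 0.08) and did not pass. All 55 measured replication histone genes were positive, with H3c15 at 0.48 (SE 0.30), H4c11 at 0.35 (SE 0.29) and H4c12 at 0.27 (SE 0.22). The camera adjusted p was 0.00135 (adjusted p = 0.742 with an estimated correlation). Without WT female 2 the histone list lost its call and turned lower (camera adjusted p = 0.624), and without WT male 3 it was also lost (camera adjusted p = 0.100). By sex, 53 of 55 histone genes were positive in females (mean 0.53, camera adjusted p = 4.0e-14; adjusted p = 0.831 with an estimated correlation) and 16 of 55 in males (mean −0.087, camera adjusted p = 0.684). The histone score over both sexes gave an exact permutation p of 0.385. With the leukocyte score as a covariate the p53 and histone calls were lost (camera adjusted p = 0.603 and 0.287), and the p53 list turned higher. Without WT female 2 and KO male 1 together these calls were lost as well (camera adjusted p = 0.115 and 0.915). By sex, 6 of 24 p53 genes were positive in males (camera adjusted p = 0.00471; adjusted p = 0.499 with an estimated correlation) and 10 of 24 in females (camera adjusted p = 0.157), and the difference between the sexes was not called (camera adjusted p = 0.211).

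Proliferation genes (21 of 43 positive, camera adjusted p = 0.641; E2f1 0.25, E2f2 0.50 and Pcna 0.27) were not called over both sexes, and moved in opposite directions by sex. In females 42 of 43 were positive (mean 0.32, camera adjusted p = 1.4e-06; adjusted p = 0.879 with an estimated correlation) and in males 6 of 43 (mean −0.24, camera adjusted p = 0.0248; adjusted p = 0.860 with an estimated correlation). The difference gave a camera adjusted p of 6.4e-07, and adjusted p = 0.568 with an estimated correlation. The female rise rests on WT female 2, with a proliferation score of 3.64. WT female 1, at 4.64, lay above all KO females (4.49 to 4.59). In males the KO scores (4.87 to 5.04) lay within the range of WT males 1, 2 and 3 (5.66, 5.15 and 4.65). WT male 3 was below every KO male, so the male fall rests largely on WT male 1. Not called over both sexes either were heterochromatin and lamina genes (21 of 41 positive, camera adjusted p = 0.696; Zfp809 −0.33, Dnmt3a 0.24 and Sun2 0.19) and DNA repair genes (21 of 46 positive, camera adjusted p = 0.838; Xrcc4 0.41, Xrcc3 −0.35 and Chek2 0.25).

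Contractile genes had a mean log2 fold change of −0.97 in males (0 of 18 positive, camera adjusted p = 3.0e-18; adjusted p = 0.254 with an estimated correlation) and of 0.20 in females (15 of 18 positive, camera adjusted p = 0.101). The test of the difference between the sexes gave a camera adjusted p of 4.4e-17, and adjusted p = 0.279 with an estimated correlation, with 0 members past over all genes. Over both sexes it was −0.47, with 0 of 18 positive, and the list score gave an exact permutation p of 0.19 (adjusted p = 0.475). The actin-binding proteins Tagln and Cald1 were at −0.68 (SE 0.21) and −0.40 (SE 0.15), and tropomyosin Tpm1 at −0.56 (SE 0.22). Over both sexes the camera adjusted p was 3.3e-06, and adjusted p = 0.484 with an estimated correlation. With the leukocyte score as a covariate that call was lost and the list turned higher (camera adjusted p = 0.276). With edgeR and DESeq2 0 members passed over all genes, with edgeR 0 when adjusted over the list alone, and limma-voom with sample quality weights called 9 lower. Collagen and matrix genes were not called over both sexes (16 of 41 positive, camera adjusted p = 0.0655), with the matricellular proteins Ccn2 at −0.64 (SE 0.18) and Ccn1 at −0.44 (SE 0.16) and Sparc at −0.30 (SE 0.12). In males the matrix genes were called lower, with 14 of 41 positive (camera adjusted p = 0.0143; adjusted p = 0.657 with an estimated correlation), and in females 23 of 41 were positive (camera adjusted p = 0.920). Lung fibroblast identity genes were not called over both sexes either (12 of 25 positive, camera adjusted p = 0.696). In females they were called higher, with 22 of 26 positive and a mean of 0.48 (camera adjusted p = 0.0155; adjusted p = 0.805 with an estimated correlation). The identity score was 3.02 to 3.40 in the KO females, 2.94 in WT female 1 and 2.41 in WT female 2, which carries much of the female difference. In males the mean was −0.15, with 1 higher and 5 lower over the list alone (camera adjusted p = 0.149). Over both sexes and adjusted over that list alone, Foxf1 was lower and Gli1, a hedgehog effector, higher at 0.66 (SE 0.18), with Scara5 at 1.40 (SE 0.49) not past.

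Markers of other cell types were measured in these cultures, some of them at low levels, and 2 of these lists moved as groups. Over both sexes 18 of 20 leukocyte, 8 of 20 epithelial and 5 of 16 skeletal muscle markers passed the low-count filter. The epithelial score was −0.538 to 0.922 (log2 CPM) outside WT male 2, and the skeletal muscle score −0.363 to 0.696. Leukocyte and macrophage markers were higher as a group (17 of 18 measured positive, none shared with another list; camera adjusted p = 8.3e-08; adjusted p = 0.484 with an estimated correlation). Lyz2 was at 4217 ± 1198 CPM in KO (SD, n = 6) and 3106 ± 505 CPM in WT (SD, n = 5). Mrc1, the macrophage mannose receptor, was at 1520 ± 474 against 844 ± 397 CPM. Cd68 was at 672 ± 172 against 461 ± 84.6 CPM and the pan-leukocyte phosphatase Ptprc at 171 ± 39.0 against 118 ± 19.1 CPM. Itgam had a log2 difference of 0.45 (SE 0.15). By sex, 17 of 19 were positive in males and 14 of 19 in females, where the list was not called (median 0.049, camera adjusted p = 0.232). With edgeR 0 members passed over both sexes, over all genes or adjusted over the list alone. DESeq2 called 1 higher and limma-voom with sample quality weights 13. Epithelial markers were lower (0 of 8 positive, camera adjusted p = 0.00456; adjusted p = 0.484 with an estimated correlation), with Krt19 at −0.60 (SE 0.17) lower when adjusted over the list alone and Cdh1 at −0.74 and Krt7 at −0.90 not past. That call was lost without WT male 2 (camera adjusted p = 0.124), whose epithelial score stood apart from the other WT libraries. In females 7 of 10 epithelial markers were positive, with a mean of 0.33 (camera adjusted p = 0.758), and in males 0 of 10. The epithelial score over both sexes gave an exact permutation p of 0.25. Markers of endothelial cells (4 of 16 positive, mean −0.60, camera adjusted p = 0.0525; Vwf 0.75, Kdr 0.43 and Egfl7 −0.57), mesothelial cells (1 of 10 positive, 0.278; Cldn15 −0.70, Lrrn4 −0.89 and Bnc1 −0.85, with Cldn15 at 0.23 without WT female 2) and pericytes (2 of 9 positive, 0.334; Notch3 0.27, Mcam −0.67 and Trpc6 −0.86) were not called. Neither were those of skeletal muscle (3 of 5 positive, 0.358; Acta1 −1.39, Tnnt3 −0.71 and Tnni2 0.18), cartilage (3 of 10 positive, 0.278; Acan −1.21, Col9a3 −0.77 and Col11a2 −0.63) and adipocytes (5 of 7 positive, 0.0915; Cebpa 0.39, Fabp4 0.67 and Lipe 0.41, the last higher when adjusted over the list alone).

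Stress and mitochondrial lists were called lower over both sexes and not in each sex. NRF2 targets of the antioxidant response were positive in 7 of 19 cases (camera adjusted p = 0.00744; adjusted p = 0.484 with an estimated correlation), with the thioredoxin reductase Txnrd1 at −0.53 (SE 0.16), the cystine transporter Slc7a11 at −0.55 (SE 0.18) and Gclc, of glutathione synthesis, at −0.32 (SE 0.11). Gclc lies 0.662 Mb from Cgas, where a knockout can carry flanking sequence of another strain. The NRF2 score gave an exact permutation p of 0.005, the smallest the design allows (adjusted p = 0.0938). The NRF2 camera call was lost without WT female 2 (camera adjusted p = 0.372). Genes of the integrated stress and unfolded protein responses were positive in 3 of 22 cases (camera adjusted p = 0.00475; adjusted p = 0.484 with an estimated correlation), with the chaperone Hyou1 at −0.24 (SE 0.07), Ddit3 at −0.46 (SE 0.17) and Sdf2l1 at 0.27 (SE 0.10), and the call was lost without WT female 1 (camera adjusted p = 0.123) and with the leukocyte score as a covariate (camera adjusted p = 0.0848). All 13 mitochondrially encoded genes were negative (camera adjusted p = 0.00428; adjusted p = 0.484 with an estimated correlation), mt-Nd5 at −0.27, mt-Nd4 at −0.24 and mt-Nd6 at −0.37. Immediate early genes were not called (camera adjusted p = 0.977; Fosl1 −0.47, Jun 0.34 and Klf10 −0.50). By sex, NRF2 targets had a mean of −0.077 in males (camera adjusted p = 0.709) and −0.30 in females (camera adjusted p = 9.0e-06; adjusted p = 0.598 with an estimated correlation). The stress response genes had a mean of −0.31 in males (camera adjusted p = 0.00106; adjusted p = 0.499 with an estimated correlation) and 0.0094 in females, with 11 of 22 positive (camera adjusted p = 0.860). The mitochondrial genes were at a mean of −0.27 in males (camera adjusted p = 0.00517; adjusted p = 0.553 with an estimated correlation), and in females 4 of 13 were positive (camera adjusted p = 0.331). Over both sexes edgeR passed 0 members of these 4 lists over all genes or adjusted over the list alone, while DESeq2 called 1 stress response gene and 1 immediate early gene lower. With limma-voom and sample quality weights, 5 stress response and 2 mitochondrial genes were lower, 2 immediate early genes higher, and NRF2 targets split into 3 higher and 2 lower.

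Within males, sterol, macrophage and contractile genes were called as groups with the preset correlation. With an estimated correlation no list was called in males (lowest adjusted p = 0.191). Of the 20 cholesterol genes 15 rose over all genes tested and 19 when adjusted over the list alone, with a mean log2 fold change of 0.89. Insig1, a sterol sensor, rose from 62.3 ± 9.11 to 142 ± 11.5 CPM (SD, n = 3 each; edgeR adjusted p = 0.0349). Hmgcs1, of the mevalonate pathway, rose from 92.1 ± 19.8 to 187 ± 17.1 CPM. Of 19 leukocyte markers 5 rose over all genes and 12 when adjusted over the list alone, among them the macrophage receptor Adgre1, from 209 ± 27.4 to 425 ± 112 CPM. Of 18 contractile genes 5 fell over all genes and 16 when adjusted over the list alone, with a mean of −0.97. The smooth muscle myosin Myh11 went from 103 ± 36.3 to 27.4 ± 10.4 CPM and calponin Cnn1 from 220 ± 68.6 to 79.5 ± 21.3 CPM. Acta2, smooth muscle actin, was at 1004 ± 286 CPM in KO and 2229 ± 633 CPM in WT males and missed the threshold (edgeR adjusted p = 0.0620).

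The highest male fold changes past the threshold were Ighm, the immunoglobulin mu chain (log2 2.54, SE 0.34; 6.82 against 1.17 CPM), Fgl2 (1.91, SE 0.40), the deiodinase Dio3 (1.73, SE 0.26), the pentraxin Ptx3 (1.68, SE 0.31) and Fabp5, a fatty acid binding protein (1.53, SE 0.28; 915 against 318 CPM). The lowest were the serotonin receptor Htr1b (−2.43, SE 0.52), Lgr6 (−2.27, SE 0.47), cholecystokinin Cck (−2.10, SE 0.43), Myh11 (−1.92, SE 0.33) and Cgas. Camera adjusted p-values in males were 7.8e-32 for cholesterol genes, 4.0e-10 for leukocyte markers and 3.0e-18 for contractile genes, and with an estimated correlation the adjusted p = 0.191, 0.254 and 0.254.

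Markers of other cell types were also called in males with the preset correlation. Those of endothelial cells were positive in 3 of 16 cases, with a mean of −1.38, and 1 was higher and 10 lower when adjusted over the list alone (camera adjusted p = 0.00159; adjusted p = 0.553 with an estimated correlation). Pericyte markers were positive in 2 of 9 cases, with a mean of −0.75, and 1 was higher and 4 lower over the list alone (camera adjusted p = 0.0367; adjusted p = 0.254 with an estimated correlation). Epithelial markers had a mean of −1.79, with 3 lower over the list alone (camera adjusted p = 0.00115; adjusted p = 0.379 with an estimated correlation). WT male 2 stood apart there, with an epithelial score of 2.34 against 0.206 and 0.580 in the other WT males and −0.397 to 0.286 in the KO males, and it also had the highest endothelial score of the males (2.18). Mesothelial markers had a mean of −1.28, with 0 past (camera adjusted p = 0.0248; adjusted p = 0.657 with an estimated correlation). Adipocyte markers were positive in 7 of 7 cases, with a mean of 0.68 and 3 higher over the list alone (camera adjusted p = 0.00153; adjusted p = 0.254 with an estimated correlation). Myh11, Cnn1 and Acta2 are also expressed by pericytes and vascular smooth muscle cells.

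In all, 459 of 22960 entries passed in males (299 higher, 160 lower), with adjusted p-values close under 0.05. The count was 0 without KO female 2, KO female 3, KO male 1, KO male 2 or WT male 1, it was 1 without WT male 3 and 17 without KO female 1. It rose to 1012, 1091, 1766 and 2065 without WT male 2, KO male 3, WT female 2 and WT female 1. With RLE size factors it was 284 (158 higher, 126 lower). With the leukocyte score as a covariate edgeR called 0 (1085 at an unadjusted p under 0.05), with replicate number as a block 0 (5008) and on the males alone 0 (5413). DESeq2 called 2035 entries and limma-voom with sample quality weights 4584.

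Within females, Cgas was the 1 entry past the threshold of 22960 (1529 had an unadjusted p under 0.05; DESeq2 called 6 and limma-voom with sample quality weights 0). The cholesterol genes were positive in 19 of 20 cases, at a mean of 0.36, and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 8.9e-10; adjusted p = 0.722 with an estimated correlation). Not past the threshold (edgeR adjusted p = 0.692) were the G-protein regulator Rgs5 at 1.95 (SE 0.41), Ano1 at 1.40 (SE 0.40), Asap2 at 0.62, Pcdhb22 at 0.55, Slc16a13 at 0.47, Ptpru at −1.02, mt-Rnr2 at −0.92 and cathepsin K, Ctsk, at −0.73. Vgf, a neuropeptide precursor, was at 5.20 and 358 CPM in the 2 WT females and between 2.40 and 7.79 CPM in the 3 KO females, so that its difference rests on WT female 2. Without WT female 1 the count was 3709; the remaining WT female is then assumed to vary like the other groups. The Cgas call in females was lost, leaving 0, without KO female 1, KO female 2, KO female 3, KO male 1, KO male 2, KO male 3 or WT male 2, and without WT female 2 the 1 entry called was Clca3a2 in its place.

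The difference between the male and the female genotype effect was tested itself, and 0 of 22960 entries passed with edgeR (3016 at an unadjusted p under 0.05; DESeq2 called 220 and limma-voom 0). Without WT female 1 the count was 2435, and without WT female 2 it was 1. Smallest in p, at an edgeR adjusted p of 0.294, were Pla1a, a phospholipase (male minus female log2 3.91, SE 0.67), Srpx2 (2.18), N4bp2l1 (1.95), Hscb (1.18) and Optn (0.99), and on the other side Ano1 (−2.85), the imprinted gene Peg3 (−2.14), Mast4 (−1.39), Asap2 (−1.33) and Myo1d (−1.15). Contractile genes had a mean difference of −1.17, all 18 being lower in the male than in the female contrast, and 16 passed when adjusted over the list alone (camera adjusted p = 4.4e-17; adjusted p = 0.279 with an estimated correlation). For leukocyte markers the mean difference was 0.44, with 8 members past when adjusted over the list alone, and for cholesterol genes it was 0.53, with 3 past (camera adjusted p = 3.3e-05 and 3.3e-08; adjusted p = 0.568 with an estimated correlation for each).

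**Figure D2:**
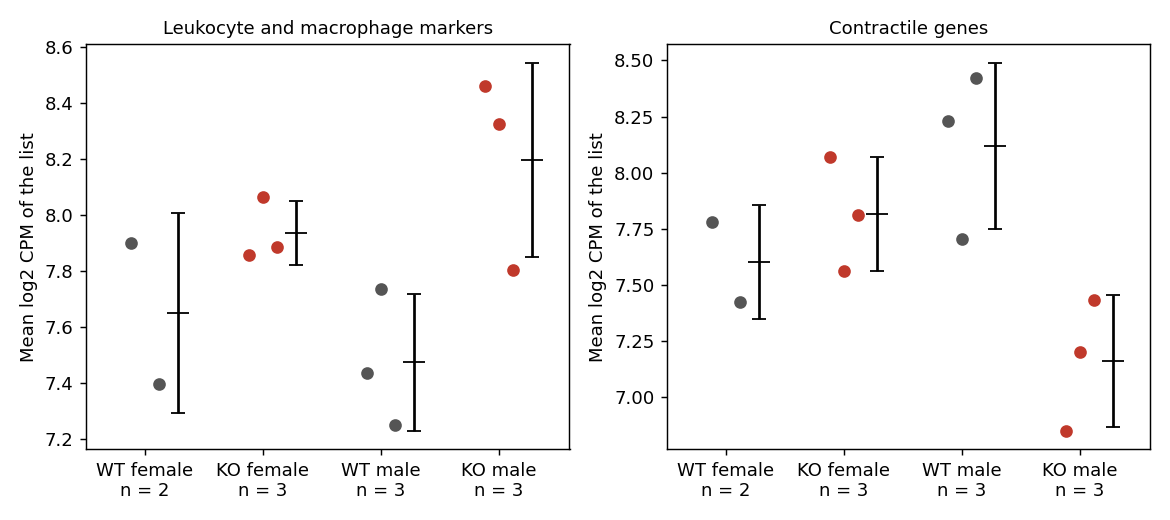
Mean log2 CPM of the leukocyte and macrophage markers (left) and of the contractile genes (right) by group, with 1 point per library and the mean ± SD in black beside the points. The 3 KO males span 7.81 to 8.46 for leukocyte markers and 6.85 to 7.43 for contractile genes, and the 3 WT males span 7.25 to 7.74 and 7.71 to 8.42.

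Males and females differed first in sex-linked genes, which checked the labels. Ddx3y, Eif2s3y and Kdm5d on the Y chromosome were at 76.4 ± 8.03, 28.2 ± 2.76 and 24.9 ± 2.99 CPM in males (SD, n = 6) and had 0 counts in the 5 females, which allows at most 0.0636 to 0.110 CPM per library. Uty was at 25.3 ± 2.95 CPM in males and 0.00508 CPM in females, under that level. Xist, which silences the X chromosome, was at 449 ± 106 CPM in females and 0.0187 CPM in males, also under it, and its antisense partner Tsix at 32.4 ± 5.26 CPM in females and 0 counts in males; reads of the pair cannot be told apart without strand. Past the threshold were also the cartilage collagen Col2a1, higher in males (log2 2.76, SE 0.63), and the chitinase-like Chil3 (−2.89, SE 0.65), Atp1b2 (−1.89, SE 0.44) and Syt13 (−1.69, SE 0.40), lower in males. In total 408 entries were higher and 548 lower in males (956 of 22298), and all 171 repeat subfamilies among them were lower in males. The repeat calls numbered 8 without WT female 2, 11, 4 and 5 without KO female 1, KO female 2 and KO female 3, and 4 each without KO male 2, KO male 3 and WT male 2. They numbered 52, 15, 288 and 699 without KO male 1, WT male 1, WT male 3 and WT female 1. Higher entries outnumbered lower ones without the low-count filter (506 and 488), with DESeq2 (1388 and 1386) and without WT male 1 (265 and 232), KO male 2 (53 and 51) or KO male 3 (98 and 89). The count of 956 was 901 with RLE size factors and 994 without the low-count filter. It was 104, 148, 159, 163, 187 and 220 without KO male 2, KO female 3, WT male 2, KO female 2, KO male 3 and KO female 1. It was 401, 431 and 497 without WT female 2, KO male 1 and WT male 1, and 1650 and 3340 without WT male 3 and WT female 1.

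LINE-1 elements, the retrotransposons named in the series title, took 0.607 ± 0.117% of counts in KO (SD, n = 6) and 0.682 ± 0.147% in WT (SD, n = 5). The log2 difference was −0.20 (two-sided exact permutation p = 0.135), and for the young L1Md subfamilies it was −0.17 (exact permutation p = 0.195). In males the LINE-1 share was 0.511 ± 0.0581% in KO and 0.615 ± 0.0448% in WT (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). Without WT female 1 the difference was −0.35 (exact permutation p = 0.0125), and without WT female 2 it was −0.05 (exact permutation p = 0.638). Old inert families (MIR, L2, hAT-Charlie and TcMar-Tigger), which no longer transpose, were at 0.352 ± 0.0704% in KO and 0.404 ± 0.0819% in WT (log2 −0.23, exact permutation p = 0.105). None of 22 repeat families passed (lowest adjusted p = 0.211).

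**Figure D3:**
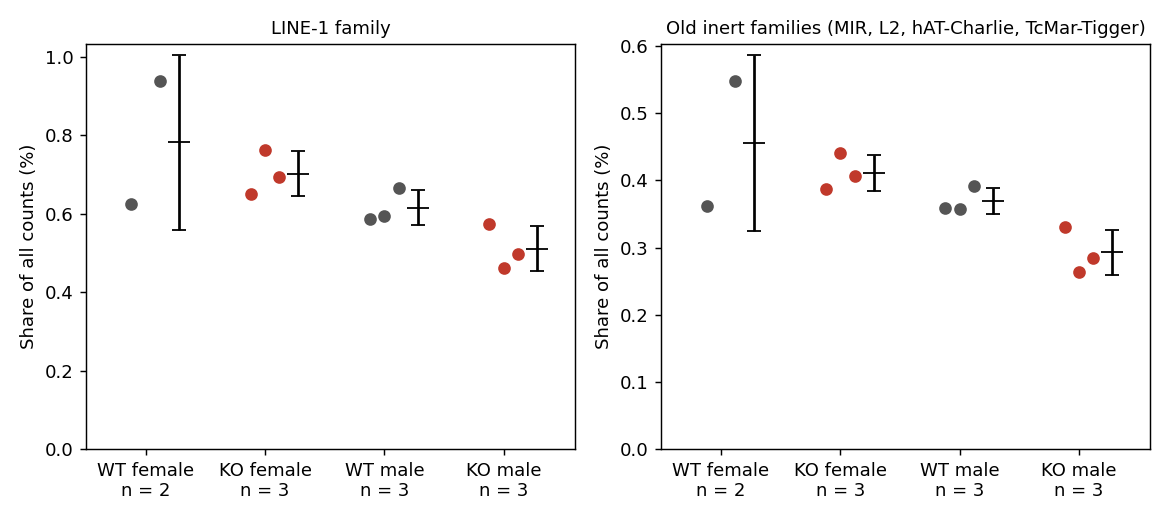
Share of all counts on the LINE-1 family (left) and on old inert repeat families (right) in percent by group, with 1 point per library and the mean ± SD in black beside the points. WT female 2 is highest in both, at 0.939% and 0.548%, and the 3 KO males (0.461% to 0.574% for LINE-1) lie below the 3 WT males (0.586% to 0.667%).

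Among 1085 repeat subfamilies 0 passed with edgeR, over all entries or over repeats alone (lowest adjusted p = 0.218), and 90.4% had a negative log2 difference, with a median of −0.26. At an unadjusted p under 0.05 there were 219, of which 213 were lower in KO. DESeq2 called 6 and limma-voom with sample quality weights 86, and without WT female 1 the count was 211. The mouse major satellite GSAT_MM was at 2.64 ± 0.64 CPM in KO and 5.61 ± 1.91 CPM in WT (log2 −1.13, SE 0.21), followed by RMER16B3 (−1.13, SE 0.29), Charlie19a (−0.63), RLTR20A2 (−0.62) and MER54A (−0.60). On the higher side were the retroviral subfamilies RLTR1B (0.56, SE 0.14), LTR37A (0.50), RLTR45-int (0.49), LTR16A2 (0.36) and RLTR44C (0.31). Within males 5 subfamilies passed over all entries, and 0 when adjusted over repeats alone (edgeR, lowest adjusted p = 0.218; 131 at an unadjusted p under 0.05). RLTR1B (0.79, SE 0.17), RLTR45-int (0.79, SE 0.18) and LTR37A (0.85, SE 0.18) were higher in KO and IAPEY4_I (−1.02, SE 0.21) and IAPEY4_LTR (−0.97, SE 0.20) were lower.

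Genes near Cgas were compared with the rest because a knockout can carry flanking sequence of another mouse strain. Over both sexes 0 of 142 genes within 10 Mb and 0 of 20317 others passed with edgeR, and 19.0% against 17.2% had an unadjusted p under 0.05 (Fisher exact p = 0.576). In males 8 of 142 neighbours and 436 of 20317 others passed (Fisher exact p = 0.0124). With a window of 5 Mb it was 3 of 52 (Fisher exact p = 0.103) and with 20 Mb 15 of 318 (Fisher exact p = 0.00513). At an unadjusted p under 0.05 the male shares were 26.8% against 23.3% within 10 Mb (Fisher exact p = 0.320), 36.5% within 5 Mb (Fisher exact p = 0.0315) and 26.1% within 20 Mb (Fisher exact p = 0.229). The male calls behind these counts fell to 0 without KO female 2, KO female 3, KO male 1, KO male 2 or WT male 1. The neighbour with the smallest p over both sexes was Ddx43, 0.0272 Mb from Cgas, at a log2 difference of 2.15 (SE 0.50, edgeR adjusted p = 0.179) and a low average of −2.08 log2 CPM. Nnt, which carries a deletion in some C57BL/6 stocks, was at 14.1 ± 1.73 CPM in KO and 13.1 ± 5.09 CPM in WT (log2 0.20, SE 0.22, edgeR adjusted p = 0.666), so a difference beyond the spread was not detectable. Its log2 difference was −0.062 without WT female 2.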

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

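The tests of the male calls without WT female 2 and with a leukocyte score were chosen after those calls were seen and before their own results, and the ratio of LINE-1 to old inert families was chosen after its result was seen.

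Single libraries stood far from the others of their genotype in 23 of 108 groups of values tested (21.3%), and 20 of the 23 came from WT female 2. Chance gives about 1 in 20 for a single group. The groups are not independent, because many are repeat shares of the same libraries and some are parts or sums of others. The 21.3% therefore cannot be set against that rate, and mostly counts 1 library many times. KO female 3 had the lowest total of the KO libraries, 27.26 M (mega) counts, the others having at least 45.28 M counts.

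WT female 2 had the highest share of counts of the 5 WT libraries in most repeat families. Its share was 0.939% for LINE-1, 0.1257% for young L1Md subfamilies, 1.102% for Alu, 0.7704% for B2, 0.02051% for CR1 and 0.09188% for ID. It was 0.4005% for ERVK, 0.1338% for ERVL, 0.6527% for ERVL-MaLR, 0.03102% for Gypsy, 0.02127% for L1-dep and 0.1372% for L2. It was 0.1976% for MIR, 0.004965% for RTE-Bo.B, 0.03345% for satellites, 0.04251% for TcMar-Tigger, 0.007634% for hAT-Ac, 0.1707% for hAT-Charlie and 0.548% for the old inert families together. Its NRF2 score of 6.231 was the highest of WT, the others reaching 5.86. WT male 2 had an epithelial score of 2.344 against at most 0.580 in the other WT libraries, and KO male 1 a cartilage score of 0.6709 against at most 0.222 in the other KO libraries.

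The genotype effect differed between males and females in 16 of 25 lists by a camera test of the difference with the preset correlation, and in 0 with an estimated correlation (lowest adjusted p = 0.279). The mean log2 difference, male minus female effect, was above 0 for interferon-stimulated genes (0.1861), NF-κB targets (0.2226), leukocyte markers (0.4356), adipocyte markers (0.9873), NRF2 targets (0.2216) and cholesterol genes (0.5328). It was below 0 for proliferation (−0.5553), replication histones (−0.6199), collagen and matrix (−0.244), contractile genes (−1.174), lung fibroblast identity (−0.6225) and the stress responses (−0.3193). It was also below 0 for markers of epithelial cells (−2.127), endothelial cells (−1.703), mesothelial cells (−2.44) and pericytes (−1.065). For proliferation and replication histones the female side rests on WT female 2, with scores of 3.64 and 3.05. WT female 1, at 4.64 and 4.53, was close to the KO females (4.49 to 4.59 and 4.48 to 4.61). WT female 2 also lay outside the KO female range, with WT female 1 inside or nearer, in some other lists. For NRF2 targets, adipocyte and leukocyte markers WT female 2 had 6.23, 5.16 and 7.40, and WT female 1 had 5.80, 4.47 and 7.90. The KO females had 5.71 to 5.78, 4.30 to 4.77 and 7.86 to 8.07. In the same order of libraries, contractile scores were 7.42, 7.78 and 7.56 to 8.07, and stress response scores 6.22, 6.71 and 6.45 to 6.62.

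The male calls without a matching set in females were weighed first. Of the 458 entries called in males with Cgas left out, 61.1% had the same sign in females and 61.79% without WT female 2. That is under the bound of 65% set beforehand, but all female signs then rest on WT female 1 as the single WT female, which the bound did not allow for. The median signed log2 fold change of these entries in females was 0.054, and 0.047 without WT female 2, against 0.887 in males. Because the value without WT female 2 also rests on WT female 1 alone, whether WT female 2 hides a male-like effect stays open. With the leukocyte score in the model, the median signed log2 fold change of these entries in males fell from 0.887 to 0.4859, between the bounds set for and against a different share of leukocyte RNA. That explanation cannot be told apart from a change within the fibroblasts, because the score itself differs between genotypes. A difference between the sexes stays open as well, and sex may coincide with preparation. Lyz2 and Mrc1, at 4217 and 1520 CPM in KO, are abundant macrophage transcripts in these cultures, and the leukocyte list shares 0 members with the other lists.

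The 10 splits of the 6 males are too few for a share under 0.05: the real split called 459 entries, and the highest of the others called 0 (1 of 10 as large). Of 100 splits of males and females, 3 called as many entries as the real 956, the real split included. That is a share under 0.05, but the highest of the others called 1906. A structure of the samples beside sex can thus give more calls than sex does, and the count of 956 cannot be credited to sex alone.

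A lower LINE-1 share in KO males was weighed against a background of intronic or genomic fragments. Old inert families were lower too, at 0.293 ± 0.0338% in KO and 0.369 ± 0.0194% in WT males, and the log2 ratio of LINE-1 to them was 0.0674 higher in KO (SE 0.0171). For the young L1Md subfamilies it was 0.15 higher (SE 0.0401). Over both sexes the ratios were 0.029 and 0.062 higher (exact permutation p = 0.145 and 0.175). LINE-1 did not fall beyond the inert families, so a difference in background may account for the lower share. A rise of LINE-1 relative to that background in males stays open. The counts do not separate LINE-1 transcripts of their own from such fragments.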

How the results depend on the processing

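The covariate scores and the exclusion of WT female 2 with KO male 1 were chosen after seeing the data. For 157 genes and repeats, 2789 of 3266 comparisons with an alternative kept direction and side of the threshold, 267 lost a call, 190 gained one and 20 changed direction. Results that were not past the threshold and stayed so count as kept, and over both sexes only Cgas was past it. For the lists called, 174 of 216 were kept, 37 lost the call and 5 changed direction. Unless stated, the cause was not tested.

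DESeq2 called 521 entries over both sexes, 2035 in males, 6 in females (Cgas, Gm47283, Irx2, Rgs5, Snap91 and Vgf), 220 for the genotype-by-sex contrast, 2774 for sex and 6 repeat subfamilies. RLE size factors gave 284 in males. Without the low-count filter there were 3 over both sexes (Cgas, Gm21887 and Gm47283), 1079 in males and 2 for the genotype-by-sex contrast (Hoxd8 and Pla1a). limma-voom with sample quality weights gave 3259, 4584 and 0 over both sexes, in males and in females (2.03% of entries in females at an unadjusted p under 0.05) and 86 repeat subfamilies. In its fit over both sexes the weight was 5.52 for WT male 2 and 0.141 to 0.552 for the other WT libraries. The replicate block gave 0, 0 and 0 with edgeR (2696, 5008 and 451 unadjusted), and each sex alone 0 in males and 0 in females (5413 and 723 unadjusted). Replicate numbers showed no pairing of libraries, and the block leaves fewer residual degrees of freedom. Camera with an estimated correlation called 0 lists and fry 1 (cholesterol). The leukocyte covariate left 0 over both sexes and 0 in males (289 and 1085 unadjusted). Cgas was then at −2.07 (adjusted p 0.114), and at −1.96 (adjusted p 0.0739) with the block. Excluding WT female 2 and KO male 1 gave 0 in males (5058 unadjusted), 1 for the genotype-by-sex contrast (Clca3a2) and 211 for sex, with fewer samples.

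Without 1 library at a time the counts ran from 1 to 1678 over both sexes, 0 to 2065 in males, 0 to 3709 in females, 0 to 2435 for the genotype-by-sex contrast, 104 to 3340 for sex, 0 to 211 for repeats and 11 to 15 for lists, each highest count except that of the lists being without WT female 1. WT female 2 then stands alone in its group, is assumed to vary like the other groups, and its distance from WT female 1 no longer enters the spread. The LINE-1 difference ran from −0.35 (without WT female 1) to −0.053 (without WT female 2) and Cgas from −2.10 to −1.89.

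Changes of direction with the leukocyte covariate were, as camera p, interferon-stimulated 0.0194, p53 0.506, contractile 0.155 and leukocyte 0.568, the last being the covariate itself. As log2 values they were RLTR45-int −0.024, LTR37A −0.017, Sparc 0.0078, Kdr −0.046, Itgam −0.024, Cldn15 0.037, Lrrn4 0.63, Bnc1 0.51, Mcam 0.067, Acta1 0.055, Tnni2 −0.11, Cebpa −0.13, Fabp4 −0.047, RLTR4_Mm −0.27 and Lyz2 −0.15. With limma-voom H4c11 was at −0.017. Without 1 library at a time, the camera p of the replication histones ran from 4.43e-13 (without WT male 1) to 0.574, turning without WT female 2. Cldn15 ran from −0.96 (without KO male 3) to 0.23 and Nnt from −0.062 to 0.39 (without WT female 1), both turning without WT female 2. Excluding KO male 1 as well, Cldn15 was at 0.22 and Nnt at −0.054. Depth limits genes near 3 counts per library, such as Ddx43.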

Other observations

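Among the results in this part, RLTR4_Mm was chosen after its values were seen, and the covariate tests were chosen after the cholesterol shift was seen and before their own results.

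The cholesterol genes were higher in 19 of 20 members over both sexes, with a list score without overlap between the 6 KO and the 5 WT libraries. These genes share control by the sterol-sensing SREBP factors, so that they tend to move together, and the estimated correlation between them is what takes the camera test to an adjusted p of 0.191.

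A different share of leukocyte RNA was tested as a cause of the cholesterol shift. The KO coefficient of the cholesterol score was 0.676 (SE 0.133) with sex alone and 0.4048 (SE 0.156) with the leukocyte score beside it. That is more than 2 SE above 0, the bound set beforehand against leukocyte RNA as the whole cause. The leukocyte score itself differed between genotypes (KO coefficient 0.529), so the covariate cannot decide between a leukocyte share and a change within the fibroblasts. With the proliferation score as covariate the KO coefficient of the cholesterol score was 0.6873 (SE 0.138). The proliferation score itself hardly differed between genotypes over both sexes (KO coefficient 0.0818), so this covariate could hardly move that coefficient. It argues against the proliferation state only as a cause common to both sexes. An effect within 1 sex, where the proliferation genes moved in opposite directions, was not tested. What raises these genes stays open, and growth conditions of single cultures were not tested.

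Among 100 splits of KO and WT within sex, 1 (the real one) called as many entries over both sexes as the real value of 1, the highest of the others being 0. That entry is Cgas, the targeted gene, so this checks the labels and is no test of other changes. For repeat subfamilies the real value was 0 and all 100 splits called as many, the highest other being 0. Every split calls at least 0, so this comparison could not come out otherwise and decides nothing. For the gene lists, 43 of 100 splits called at least the real 12, the highest other being 16 and the median 11, so chance cannot be excluded for the number of lists called with the preset correlation.

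RLTR4_Mm, a subfamily of murine leukemia virus type, was at 1062 CPM in KO male 1 and between 62.4 and 122 CPM in the 5 WT libraries (log2 difference 1.24, SE 0.57, edgeR adjusted p = 0.295 over both sexes). WT female 2 had the lowest proliferation score (3.64) and a voom quality weight of 0.141, and lay at −94.8 on the first principal component, which held 34.8% of the variance.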
